A study of Mus musculus with 21 samples.

How the data were processed

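Gene expression was measured in 21 samples of mouse muscle stem cells with 1 Affymetrix Mouse Gene 1.0 ST array per sample. The cells were sorted by YFP after Pax7-driven Cre recombination, tamoxifen having been given at least 2 weeks before, and 100 ng of RNA went to each array, per the labels. Pools held 3 to 4 mice aged 3 to 5 months. The deposited log2 values are probeset signals made with RMA in Affymetrix Expression Console, per the submitters' processing notes. The program's version, its library files and the genome build are not given in the sources used here, nor is which arrays were normalized together. Array medians ran from 7.03 to 7.21 and single values from 2.95 to 14.5.

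Of 35556 probesets, 21789 have 1 gene symbol in the platform table given, 1621 have several and 12146 are not listed there, so that only the first were named. They cover 19938 genes, of which 999 have several probesets. Such a gene was represented by its brightest probeset. Genes whose mean over the 12 pools lay under the 30th percentile (log2 6.45) were left out, and 13956 were tested.

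Arrays of the same pool are technical replicates and were averaged, so that the pool was the unit: 9 pools had 2 arrays and 3 had 1. Correlations between arrays of a pool ran from 0.973 to 0.998. A model with a mean for each of 8 groups was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p was adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. All 4 residual degrees of freedom come from the WT QSC and WT CSC pools (prior 5.01, moderated 9.01, median moderated SD 0.189). The median SE of a difference was 0.154 for WT CSC against WT QSC, 0.218 for a single pool against WT QSC, 0.267 for a single pool against a single pool and 0.308 for a difference of responses. There were 9 contrasts: WT CSC at 2.5 and at 28 days, and each knockout's QSC, against WT QSC; CSC against QSC in the Rptor and cMet knockouts; and each of these responses minus that of WT.

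Gene lists, their members, the named-gene rule, the contrasts and all but 1 of the alternatives were chosen before the data were examined. There were 36 lists, of biological processes and of markers of other cell types, and 35 had 3 or more tested genes. They were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. The named genes are the targeted genes; per contrast up to 8 genes with the largest rise and 8 with the largest fall past the threshold whose pools or arrays lie on one side (up to 5 for single pools, and the 5 with the smallest p where fewer than 3 passed, leaving out predicted genes and microRNAs); members with the smallest p of each called list, up to 4 (3 for single pools); and a panel of stem cell and cell cycle genes in WT CSC at 2.5 days.

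Resemblance to the WT response was measured as the correlation and covariance across all tested genes and as the slope over the WT response genes and the share of them with the same sign. Slopes were also taken with 1 WT QSC and 1 WT CSC pool held out, a step tested on simulated data. Since 4 of these comparisons share the WT QSC pools, 100 unchanged groups were simulated for each. The values these gave match a WT change without any response to injury. Their correlations and shares with the same sign are therefore no baseline for these 4, and only their covariances are set beside them. The tests were tried on 10 simulated data sets of 13956 genes with 200 changed. For WT CSC against WT QSC, 78.7%, 99.0% and 99.8% of genes changed by log2 1, 2 and 3 were recovered. For TSC1 KO QSC against WT QSC the shares were 31.2%, 94.5% and 98.5%, for Rptor KO CSC against Rptor KO QSC 11.6%, 86.0% and 97.6%, and for the cMet KO response minus the WT response 3.28%, 70.6% and 95.2%. False calls made up 5.30%, 4.15%, 4.96% and 5.02% of calls in these 4 comparisons. The simulated data gave all pools the same spread for a gene and drew each gene by itself, as the test assumes. They do not show recovery or false calls where single pools vary otherwise or genes vary together.

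The alternatives were quantile normalization of the values again, centring of each array on its median, no filter or one at the 50th percentile, the mean of all probesets of a gene, eBayes with trend and robust options, all arrays with the pool as a random block, the first array of each pool alone, every array as a replicate, leaving out each WT pool in turn, the replicate number as a block and the 6 WT pools alone. Leaving out 3 second arrays that differ alike from their first was added after the data were seen. No scanner files were used. Figures were drawn with matplotlib 3.10.9.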

Results

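The arrays measured gene expression in mouse muscle stem cells, also called satellite cells, which were sorted by flow cytometry as YFP-positive cells after Pax7-driven Cre had switched on the tracer. RNA was taken straight after the sort, with no culture. Cells came from noninjured mice (quiescent satellite cells, QSC) or from the limb opposite to one injured with barium chloride (contralateral satellite cells, CSC), 2.5 or 28 days after the injury. The study asks whether an injury elsewhere in the body moves quiescent stem cells into an alert state, and what part is played by the mTORC1 kinase complex and by cMet, the receptor of hepatocyte growth factor. Conditional knockouts of TSC1 (an inhibitor of mTORC1), Rptor (raptor, a subunit that mTORC1 needs) and cMet address the second part. There were 12 pools of 3 to 4 mice, measured on 21 arrays in 8 groups. WT QSC had 3 pools on 5 arrays and WT CSC at 2.5 days had 3 pools on 4 arrays. The other 6 groups had 1 pool each, measured on 2 arrays: WT CSC at 28 days, TSC1 KO QSC, Rptor KO QSC, Rptor KO CSC, cMet KO QSC and cMet KO CSC.

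A group of 1 pool has no replicate check of its own. Its tests assume that the pool varies like the WT pools, and its genotype or time cannot be told apart from the pool. The median SD between pools was 0.207 in WT QSC and 0.131 in WT CSC. The number of pools limits the precision, and with it the size of change that can be detected. All values are log2 signals, array medians ran from 7.03 to 7.21, and errors of differences are standard errors (SE) from limma. Across the 13956 genes tested, the 3 WT QSC pools correlated at 0.966 to 0.972 and the 3 WT CSC pools at 0.980 to 0.993. The first principal component of the 12 pools, with 42.5% of the variance, placed the WT CSC pools at 37.8 to 45.7, the Rptor KO CSC pool at 4.45 and the other pools at -21.9 to -5.75.

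The targeted genes were read first. Tsc1 was at 8.16 in the TSC1 KO QSC pool against 8.56 ± 0.19 in WT QSC (SD, n = 3 pools), a difference of -0.40 ± 0.24 (SE) that did not pass the test (adjusted p = 0.641). It was at 9.24 in both Rptor KO pools. Rptor was at 9.19 in Rptor KO QSC against 9.26 ± 0.33 in WT QSC (SD, n = 3), a difference of -0.07 ± 0.27 (SE, adjusted p = 0.961) whose sign turned to 0.09 without WT QSC pool 1. In Rptor KO CSC it was at 8.85, against 9.58 ± 0.23 in WT CSC (SD, n = 3). Met was at 10.25 in cMet KO QSC and 10.13 in cMet KO CSC, against 10.01 ± 0.09 in WT QSC and 10.80 ± 0.16 in WT CSC (SD, n = 3). The TSC1 KO, 28-day and remaining knockout pools lay between 8.43 and 8.81 for Tsc1, 9.10 and 9.40 for Rptor and 10.05 and 10.52 for Met where not named above. Each gene has 1 probeset, which sums probes along the transcript, while a conditional allele can remove only some exons. These levels therefore check none of the genotype labels.

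**Figure D1:**
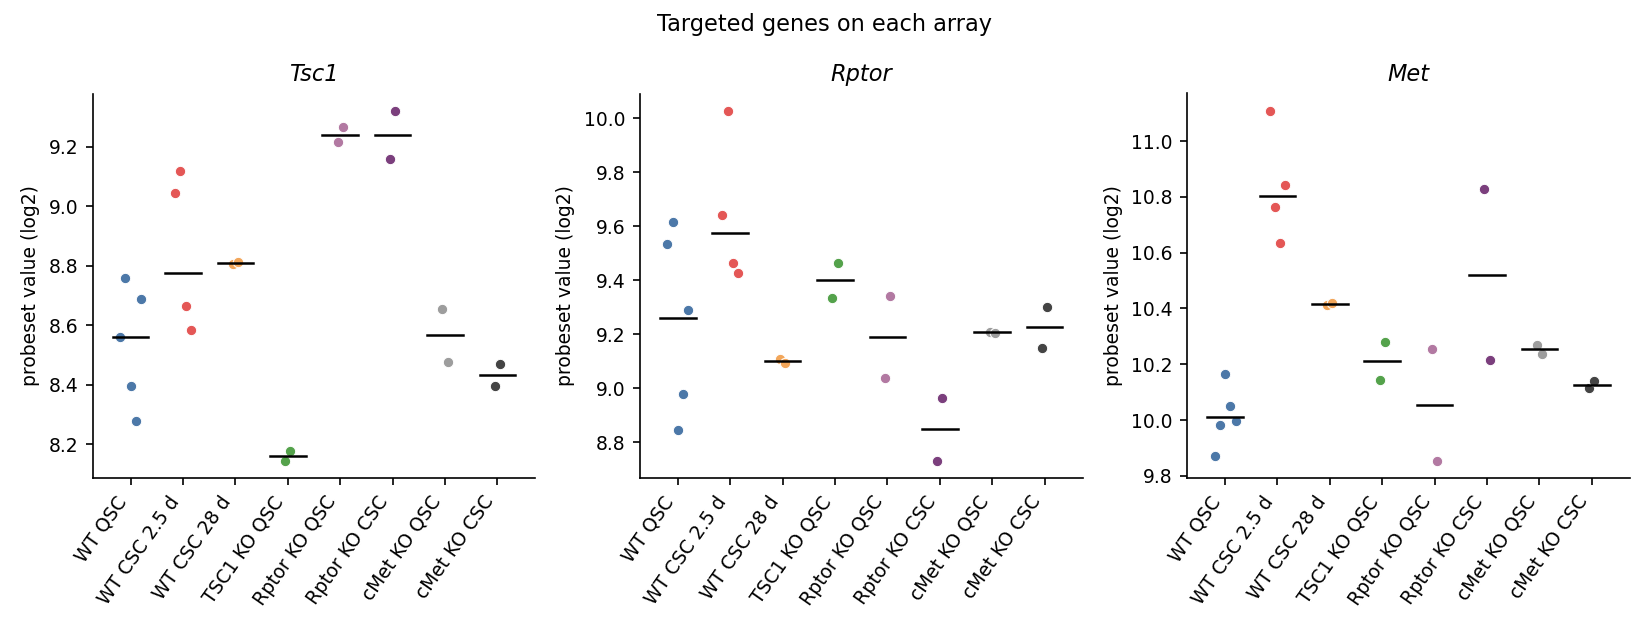
Signal of the Tsc1, Rptor and Met probesets (log2, y axis) in the 8 groups (x axis), with 1 point per array and a bar at the mean of the group's pools. Tsc1 in the TSC1 KO QSC pool (8.16) lies below the WT QSC mean (8.56), and Met in cMet KO QSC (10.25) lies above its WT QSC mean (10.01).

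Stem cells opposite an injury differed widely from those of noninjured WT mice at 2.5 days: 2510 of 13956 genes passed the threshold (limma, adjusted p under 0.05), 1483 higher and 1027 lower in CSC, and 684 of them differed by more than 2-fold. Eno3, the muscle form of enolase, rose most (12.1-fold, log2 3.59 ± 0.17, n = 3 pools against 3). Next came Plk1, a mitotic kinase (2.99 ± 0.21), Myof, or myoferlin, which acts in myoblast fusion (2.96 ± 0.20), Prrg4 (2.88 ± 0.16) and Dynap (2.85 ± 0.31). Ccne2, the cyclin E2 of S phase entry (2.69 ± 0.20), Lgals3, or galectin-3 (2.68 ± 0.17), and the aldo-keto reductase Akr1b8 (2.68 ± 0.13) rose by similar amounts. The largest falls were in Zbtb16 (PLZF, a glucocorticoid-induced transcription factor; -1.82 ± 0.29), Cd36 (a fatty acid transporter; -1.80 ± 0.20), Emcn (endomucin of endothelial cells; -1.79 ± 0.19) and Dhrs3 (a retinal reductase; -1.75 ± 0.23). Il6 (-1.75 ± 0.30), Aqp7 (-1.73 ± 0.16), the NF-kB target Birc3 (-1.66 ± 0.12) and Adgrl4 (-1.66 ± 0.15) also fell. For these 16 genes the 3 CSC pools all lay on one side of the 3 QSC pools and adjusted p ran from 3.53e-05 to 0.0051. Endothelial markers were lower in the same CSC pools (list mean -1.07), so that falls need not lie in the stem cells.

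**Figure D2:**
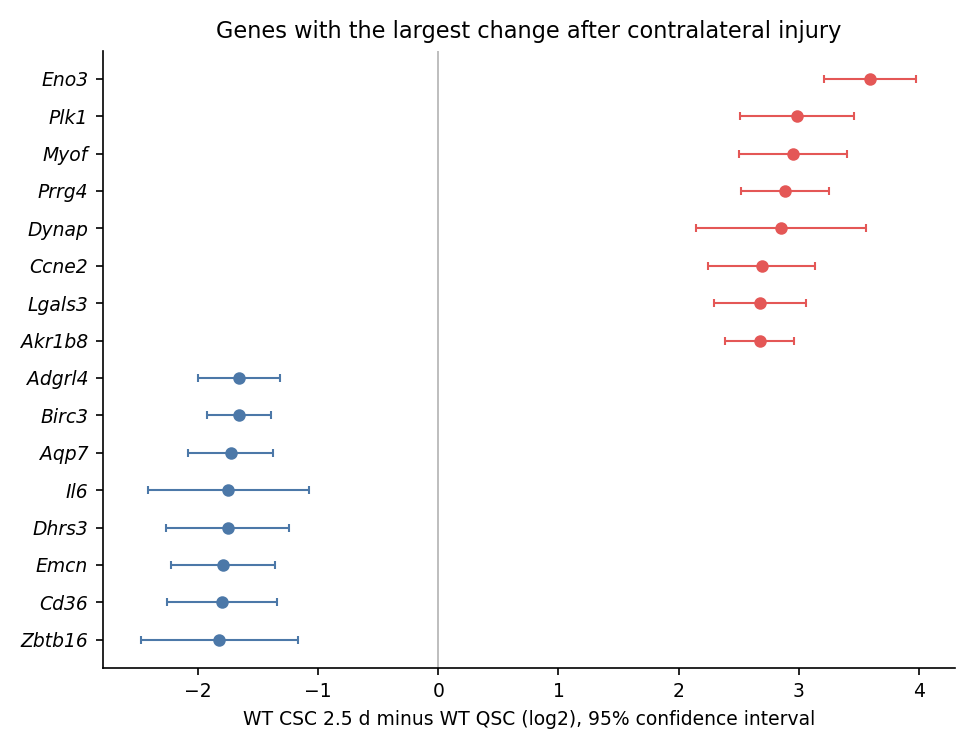
Difference between WT CSC at 2.5 days and WT QSC (log2, x axis) for the 8 genes with the largest rise and the 8 with the largest fall (y axis). Points are limma estimates from 3 pools against 3 and bars are 95% confidence intervals; Eno3 stands highest at 3.59 and Zbtb16 lowest at -1.82.

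Cell cycle genes rose as a group in these WT CSC pools. Of 36 tested members of the cell cycle and DNA replication list, 34 rose and 2 did not pass (also 34 adjusted over the list alone), with a median of 1.68. Kif20a, a kinesin of cytokinesis, rose by 2.27 ± 0.12, Ccna2, the S phase cyclin A2, by 2.05 ± 0.13, the chromatin remodeller Hells by 2.04 ± 0.13, the mitotic kinase Cdk1 by 2.17 ± 0.16 and the proliferation marker Mki67 by 1.40 ± 0.13 (n = 3 pools against 3). With limma's camera this list had the smallest p of 35 lists (adjusted p = 3.36e-34, adjusted p = 0.190 with an estimated correlation). Ccnd1, the G1 cyclin D1, did not pass (0.14 ± 0.19, adjusted p = 0.671), and without WT QSC pool 2 its difference was -0.07.

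Genes of mitochondrial energy production rose too, in pools where markers of mature muscle fibre, a tissue rich in mitochondria, were also called higher (median 0.45). In oxidative phosphorylation 42 of 73 tested nuclear-encoded genes rose and none fell (49 adjusted over the list alone, median 0.56), among them Sdhd of complex II (1.44 ± 0.18), Uqcr11 of complex III (1.14 ± 0.13) and Cox5a of complex IV (1.09 ± 0.15). In the mitochondrial ribosome 48 of 76 rose (58 adjusted over the list alone, median 0.73), as for Mrpl18 (1.50 ± 0.15) and Mrps22 (1.39 ± 0.13). In the TCA cycle 8 of 18 rose (9 adjusted over the list alone, median 0.39), including Idh3a, a subunit of isocitrate dehydrogenase (1.40 ± 0.14), and the malate dehydrogenase Mdh2 (1.09 ± 0.16). Camera called the 3 lists higher, with adjusted p = 0.190 for the first pair and 0.212 for the TCA cycle with an estimated correlation. Cycs, cytochrome c, rose by 0.57 ± 0.15 (adjusted p = 0.0323), a call that ended without WT QSC pool 1 or 3 (adjusted p = 0.0737 and 0.0615) or WT CSC pool 1, 2 or 3 (0.0596, 0.107 and 0.130). It also ended with arrays centred on their medians (0.0920), with the mean of all probesets (0.0519) and with all arrays fitted with the pool as a random block (0.0722).

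Genes of other fixed lists rose as well. In glycolysis 7 of 14 genes rose (7 adjusted over the list alone), such as Pgk1 (1.54 ± 0.16) and Tpi1 (1.49 ± 0.14), beside the higher mature fibre markers of these pools (median 0.45), a list that includes Eno3 and shares no gene with glycolysis. In the proteasome 22 of 31 rose (26 adjusted over the list alone, median 0.77), such as Psmc1 (1.08 ± 0.17) and Psma2 (0.93 ± 0.14). In ribosome biogenesis 8 of 36 rose (14 adjusted over the list alone), such as Bop1 (1.04 ± 0.16) and Wdr12 (0.82 ± 0.12), and 6 of 23 cytosolic translation factors did (6 adjusted over the list alone). In the NRF2 list 7 of 20 rose (9 adjusted over the list alone), such as Pgd of the pentose phosphate pathway (1.61 ± 0.16), malic enzyme Me1 (1.43 ± 0.13) and glutathione reductase Gsr (1.38 ± 0.16). The ATF4 and amino acid list was mixed, with 9 of 27 higher and 2 lower (11 and 2 adjusted over the list alone), and its higher members included Asns, which makes asparagine (2.04 ± 0.20), and the serine synthesis genes Phgdh (1.49 ± 0.17) and Psat1 (1.19 ± 0.13). Camera called all of these lists higher. Adjusted p was 0.432 for glycolysis, ribosome biogenesis and translation factors, 0.190 for the proteasome and NRF2 lists and 0.505 for the ATF4 list with an estimated correlation. Lists of cytosolic ribosomal proteins, mTOR pathway components, p53 targets and hypoxia targets were not called.

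Immediate early and inflammatory genes were lower in WT CSC. Of 33 genes of the immediate early and dissociation list, 21 fell (26 adjusted over the list alone, median -0.91), with Btg2, an antiproliferative gene, at -1.42 ± 0.16, the nuclear receptor Nr4a3 at -1.40 ± 0.20, Zfp36 at -1.17 ± 0.14 and Junb at -1.02 ± 0.15. Of 27 acute inflammatory genes 12 fell (16 adjusted over the list alone), including the chemokines Ccl7 (-1.31 ± 0.15) and Ccl2 (-1.29 ± 0.14). Of 23 interferon response genes 10 fell (15 adjusted over the list alone), including Irf1 (-1.03 ± 0.15). Of 21 glucocorticoid targets 8 fell (13 lower and 1 higher adjusted over the list alone), including the clock gene Per1 (-1.18 ± 0.23), and of 15 heat shock genes 7 fell (8 lower and 1 higher adjusted over the list alone), including Dnajb1 (-1.24 ± 0.15). In the circadian list 4 of 16 genes fell and 1 rose (5 and 1 adjusted over the list alone), with Bhlhe40 at -1.31 ± 0.22. Camera called these lists lower, with adjusted p = 0.276 (immediate early and inflammatory), 0.190 (interferon), 0.385 (glucocorticoid) and 0.440 (heat shock and circadian) with an estimated correlation. Endothelial markers were lower in the same pools, as given with the marker lists. The first of these lists also covers the response to dissociation, and QSC and CSC came from different mice. Whether handling or the hour of sampling differed between the groups was not tested.

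The satellite cell quiescence list was lower, with 16 of 32 genes fallen and none risen (21 adjusted over the list alone, median -0.55; adjusted p = 0.358 with an estimated correlation). Endothelial markers were lower in the same pools (median -1.04), and endothelial cells also express Tek and Cd34. Members of the quiescence list included the angiopoietin receptor Tek (-1.15 ± 0.15) and Chodl (-1.28 ± 0.17). Calcr, the calcitonin receptor that marks quiescent satellite cells, fell by 1.17 ± 0.23 (adjusted p = 0.00925). The stem cell transcription factor Pax7 (-1.07 ± 0.25, adjusted p = 0.0183) passed, but not without WT CSC pool 2 or 3 (0.0673 and 0.0741). The Notch targets Hes1 (-1.19 ± 0.27, adjusted p = 0.0180) and Heyl (-1.05 ± 0.27, 0.0286) missed the threshold without WT CSC pool 1, 2 or 3, at 0.0618, 0.0679 and 0.0532 for Hes1 and 0.0576, 0.0975 and 0.0987 for Heyl. The FGF inhibitor Spry1 (-0.70 ± 0.19, adjusted p = 0.0366) missed it without WT QSC pool 1 or 3 (0.0901 and 0.0871) or WT CSC pool 1, 2 or 3 (0.126, 0.0832 and 0.0936). The surface marker Cd34 (-0.84 ± 0.23, adjusted p = 0.0353) missed it without WT QSC pool 1 or 2 (0.0892 and 0.0852) or WT CSC pool 1, 2 or 3 (0.122, 0.0868 and 0.0579). Both also missed it with no filter on dim genes (0.0538 and 0.0542).

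Muscle genes went several ways in WT CSC. The myogenic regulators Myf5 (-0.63 ± 0.24, adjusted p = 0.108), Myod1 (0.31 ± 0.24, 0.412) and Myog (0.44 ± 0.44, 0.540) did not pass, and Myog stood at -0.13 without WT QSC pool 2. Myf5 passed with all arrays fitted with the pool as a random block (0.0101). In the list of myogenic commitment and differentiation 10 of 23 genes rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.505 with an estimated correlation). The embryonic myosin Myh3 (1.92 ± 0.22), N-cadherin Cdh2 (1.92 ± 0.24) and slow troponin Tnni1 (1.65 ± 0.17) were among those that rose. Mature fibre markers were called higher in the same pools (median 0.45). Met rose by 0.79 ± 0.13 (adjusted p = 0.00499), while Vegfa (-0.21 ± 0.15, 0.376), Tsc1 (0.21 ± 0.17, 0.435) and Rptor (0.32 ± 0.19, 0.30) did not pass. In the extracellular matrix list 8 of 30 genes fell and 2 rose (17 and 3 adjusted over the list alone, adjusted p = 0.536 with an estimated correlation), in pools where fibro-adipogenic (median -0.60) and pericyte markers (-0.70) were called lower. The gelatinase Mmp2 was one of those that fell (-0.75 ± 0.16, adjusted p = 0.0125, and 0.0517 without WT CSC pool 1).

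Markers of other cell types that a sort can carry over also moved. Of 14 endothelial markers 9 fell (12 adjusted over the list alone, median -1.04), including Cdh5, or VE-cadherin (-1.65 ± 0.25), the fatty acid binding protein Fabp4 (-1.42 ± 0.19) and Pecam1 (-1.36 ± 0.19). Of 14 fibro-adipogenic progenitor markers 7 fell (9 adjusted over the list alone), with decorin, Dcn, at -1.17 ± 0.19. Of 11 pericyte and smooth muscle markers 6 fell (8 adjusted over the list alone), with Rgs5 at -1.53 ± 0.25. Camera called the 3 lists lower, each with adjusted p = 0.358 with an estimated correlation. Markers of mature muscle fibre were called higher, with 6 of 14 risen (6 adjusted over the list alone, adjusted p = 0.505 with an estimated correlation), led by Eno3 and Actn3 (1.38 ± 0.24). None of the 14 macrophage and monocyte markers passed and their median was -0.02, a sign that turned to 0.04 after quantile normalization.

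Among the 13956 genes, 5284 (37.9%) had 3 WT CSC pools that did not overlap the 3 WT QSC pools, against 10% by chance, and 2505 of them passed the threshold. Without WT CSC pool 1, 2 or 3 the count of 2510 dropped to 1296, 1289 and 1194, of which 1272, 1278 and 1188 were among the 2510. With each array counted as a replicate it was 5794, and with arrays centred on their medians the share of higher calls was 43.4% in place of 59.1%. Camera called 23 of the 35 lists, limma's fry, which asks whether a list's genes move one way on balance, called 18, and camera with an estimated correlation called 0.

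**Figure D3:**
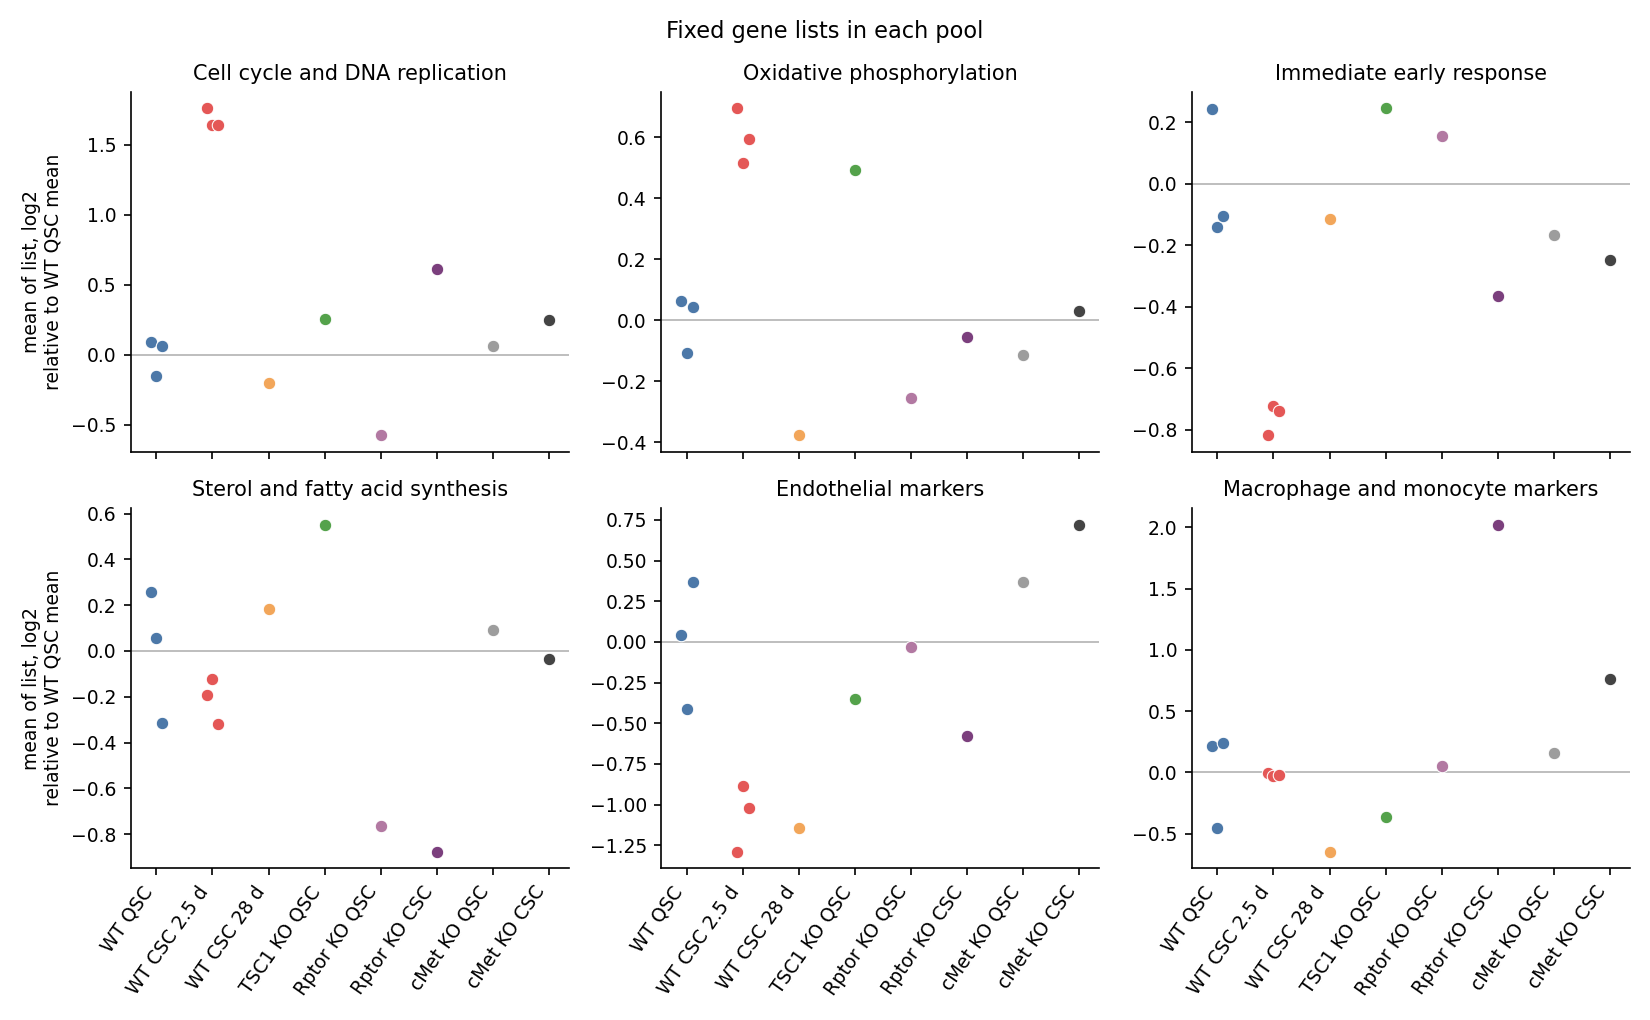
Mean of 6 fixed gene lists in each pool (log2 relative to the WT QSC mean, y axis, with a separate scale per panel) for the 8 groups (x axis), with 1 point per pool. Cell cycle genes stand at 1.64 to 1.76 in the 3 WT CSC pools at 2.5 days and at 0.61 and 0.25 in the Rptor KO and cMet KO CSC pools, and macrophage markers at 2.02 in the Rptor KO CSC pool.

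At 28 days after the contralateral injury the single WT CSC pool showed little of this. No gene passed against WT QSC (limma, 0 of 13956; 637 at an unadjusted p under 0.05, 1 pool against 3). The smallest p values belonged to the antigen presentation genes H2-Aa (-1.88 ± 0.24) and H2-Ab1 (-1.48 ± 0.21), to Emcn (-1.80 ± 0.27), Sparcl1 (-1.16 ± 0.17) and Crip1 (-1.17 ± 0.18), each with adjusted p = 0.259. Mphosph6, of RNA processing, was at 0.95 ± 0.18 (adjusted p = 0.385). All 14 endothelial markers had negative values (median -1.16, 10 adjusted over the list alone, 0 over all genes), as did the 14 macrophage markers (median -0.59, 0 adjusted over the list alone), and camera called both lists lower (adjusted p = 0.622 for each with an estimated correlation). Oxidative phosphorylation was also called lower (median -0.37, 3 of 73 adjusted over the list alone, adjusted p = 0.622 with an estimated correlation), with Uqcr11 at -1.04 ± 0.18, and cell cycle genes had a median of -0.18 (0 adjusted over the list alone, 0.622). Mature fibre (median -0.45, 0 of 14 adjusted over the list alone), pericyte (-0.40, 1 of 11) and fibro-adipogenic markers (-0.21, 0 of 14) were called lower and the Y-linked genes of the sex-linked list higher (0.63, 0 of 3), all with adjusted p = 0.622 with an estimated correlation. By list mean, inflammatory (-0.33), glucocorticoid (-0.26), extracellular matrix (-0.39) and quiescence genes (-0.19) lay below WT QSC, as at 2.5 days. Ribosome biogenesis (0.09) lay above it, also as at 2.5 days. Mitochondrial ribosome (-0.13), glycolysis (-0.19), proteasome (-0.04) and heat shock genes (0.11) had the sign opposite to that at 2.5 days. Camera called 19 lists and fry 0.

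The 28-day values did not follow the 2.5-day change. Over all genes the correlation across genes, which are not independent replicates, was 0.003 (0.134, 0.124 and -0.0230 without WT QSC pool 2, 3 or 1). The covariance was 0.000379, against 0.0148 in simulated unchanged groups that share the WT QSC pools. Of the 2510 genes that changed at 2.5 days, 48.2% had the same sign at 28 days, 39.7% of those that rose and 60.4% of those that fell. The count of 0 became 52 with the pool as a random block and 496 with each array counted as a replicate.

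Loss of TSC1 without injury left 2 genes past the threshold, both higher (limma, 2 of 13956; 1231 at an unadjusted p under 0.05, 1 pool against 3). Cox8b, a muscle and heart subunit of cytochrome c oxidase, rose 16.9-fold (4.07 ± 0.21, adjusted p = 0.000136), and the calcium channel Ryr3 rose by 2.13 ± 0.23 (adjusted p = 0.0485). Just outside the threshold were Inmt (3.50 ± 0.43), the muscle cytidine deaminase family member Apobec2 (1.63 ± 0.19) and the carrier Slc25a35 (1.57 ± 0.19), each with adjusted p = 0.0512. Lower values that did not pass included those of Vcan (-1.55 ± 0.24), Cd53 (-1.25 ± 0.19) and Nos1 (-1.24 ± 0.20), each with adjusted p = 0.123. Without WT QSC pool 1 the count was 231, with Inmt (0.000579), Apobec2 (0.0153) and Slc25a35 (0.0268) past the threshold, and also Vcan (0.0173), Cd53 (0.0283) and Nos1 (0.0377). It was 1 without any single one of the other 5 WT pools, since Ryr3 then missed it: adjusted p was 0.0789 and 0.0758 without WT QSC pool 2 or 3 and 0.120, 0.133 and 0.142 without WT CSC pool 1, 2 or 3.

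In the TSC1 KO pool camera called 18 of 35 lists, but 0 with an estimated correlation, and fry called 0. No member of the lists given here passed over all genes. Of 73 oxidative phosphorylation genes 71 had positive values (median 0.46, 7 adjusted over the list alone), with Ndufab1 at 1.04 ± 0.18 and Ndufs5 at 1.00 ± 0.20. All 27 sterol and fatty acid synthesis genes did (median 0.60, 4 adjusted over the list alone), with Scd2 at 1.26 ± 0.33 and Nsdhl at 0.93 ± 0.22. So did 42 of 44 lysosome and autophagy genes (median 0.35, 1 adjusted over the list alone), with Gpnmb, a lysosomal glycoprotein, at 2.29 ± 0.30 (adjusted p = 0.0705), and 20 of 23 myogenic genes (median 0.67, 7 adjusted over the list alone), with the embryonic light chain Myl4 at 2.36 ± 0.31. Cytosolic ribosomal proteins had a median of -0.24 (0 of 55 adjusted over the list alone), with Rpsa, a protein of the small subunit, at -0.63 ± 0.18. Camera called these 5 lists, each with adjusted p = 0.615 with an estimated correlation. Markers of mature fibre were called higher in this pool (median 0.74, 4 of 14 adjusted over the list alone), with the light chain Myl1 at 2.28 ± 0.44, and endothelial (median -0.32) and macrophage markers (median -0.31) lower, with 0 adjusted over the list alone in either, and so were lymphocyte markers (-0.24, 1 of 4), all again with adjusted p = 0.615. Without WT QSC pool 1, Gpnmb (adjusted p = 0.0153), Myl4 and Scd2 (0.0283 each), Myl1 (0.0339), Ndufab1 (0.0340) and Ndufs5 (0.0377) passed. Gpnmb and Myl4 also passed with arrays centred on their medians (0.0161 and 0.0134). Centring arrays on their medians moved the median of all genes by -0.17, and with it the list medians became 0.29 (oxidative phosphorylation), 0.43 (sterol), 0.18 (lysosome), 0.50 (myogenic) and -0.41 (ribosomal proteins).

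Set against the WT change after injury, the TSC1 KO values had a correlation of 0.113 across genes and a covariance of 0.0184 (0.0148 in simulated unchanged groups). The correlation was 0.233, 0.189 and 0.0534 without WT QSC pool 1, WT QSC pool 3 or WT CSC pool 1. The same sign was seen for 62.1% of the 2510 genes (69.4% without WT QSC pool 1). It was seen for 76.4% of those that rose in WT CSC and 41.5% of those that fell. Neither Cox8b nor Ryr3 was among the genes that rose in WT CSC (independent lists would share 0.213 genes), and both were among those that fell there.

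Loss of Rptor without injury went with lower cell cycle genes. Of 17 genes past the threshold (limma, 1 pool against 3; 1573 at an unadjusted p under 0.05), 12 fell and 5 rose. Ccna2 fell by 2.59 ± 0.19 (adjusted p = 0.00293), Mki67 by 2.16 ± 0.19 (0.00776), the spindle checkpoint kinase Bub1 by 1.91 ± 0.23 (0.0230), the DNA topoisomerase Top2a by 1.89 ± 0.18 and anillin, Anln, by 1.83 ± 0.17 (0.00945 each). Gpnmb rose 4.94-fold (2.31 ± 0.30, adjusted p = 0.0329), Mcoln2, a cation channel of endosomes and lysosomes, by 1.95 ± 0.23 (0.0225) and Cox8b by 1.62 ± 0.21 (0.0266). In the cell cycle list 5 of 36 genes fell (12 adjusted over the list alone, median -0.36). Sterol and fatty acid synthesis genes had a median of -0.85, with 1 of 27 fallen over all genes and 10 adjusted over the list alone: Fdps, farnesyl diphosphate synthase (-1.60 ± 0.20, adjusted p = 0.0230), passed and Idi1, isopentenyl diphosphate isomerase (-2.27 ± 0.39, 0.0752), did not. Camera called both lists lower, with adjusted p = 0.710 (cell cycle) and 0.725 (sterol) with an estimated correlation.

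**Figure D4:**
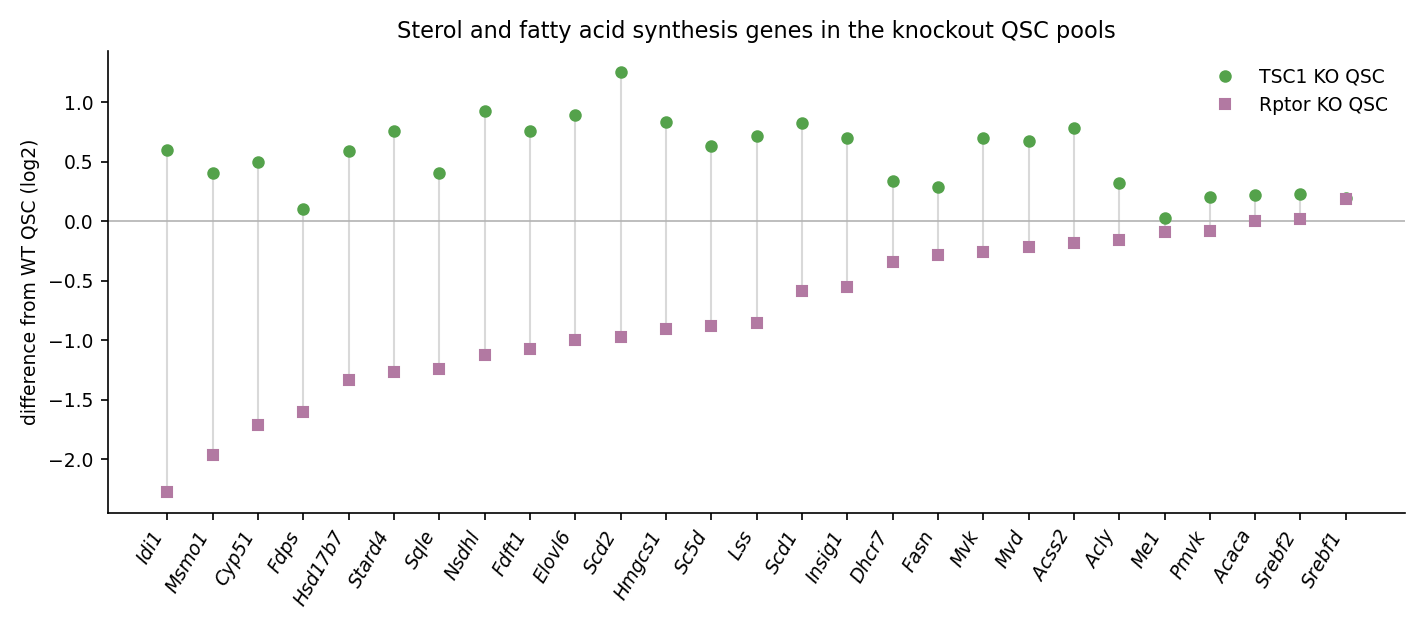
Difference from WT QSC (log2, y axis) of the 27 tested sterol and fatty acid synthesis genes (x axis, ordered by the Rptor KO value), with circles for the TSC1 KO QSC pool and squares for the Rptor KO QSC pool. Points are limma estimates for 1 pool against 3; all 27 circles are positive, and Idi1 has the lowest square at -2.27.

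Other lists in the Rptor KO QSC pool were called by camera alone, by neither fry nor camera with an estimated correlation, and none of their members passed over all genes. The proteasome (median -0.49, 7 of 31 adjusted over the list alone, 0.710), oxidative phosphorylation (-0.23, 6 of 73, 0.725) and the ATF4 list (-0.28, 4 of 27, 0.725) were called lower, where the last value is adjusted p with an estimated correlation. Psmd14 was at -1.10 ± 0.25, Cycs at -1.15 ± 0.21 and Psat1 at -1.24 ± 0.19 (adjusted p = 0.0587, and 0.0481 without WT QSC pool 2). Cytosolic ribosomal proteins were called higher, with 47 of 55 positive values (median 0.19, 0 adjusted over the list alone, adjusted p = 0.725 with an estimated correlation), and Rps21 at 0.88 ± 0.20. Neutrophil markers were called higher (median 0.37, 0 of 5 adjusted over the list alone, 0.725) and mature fibre markers lower (-0.25, 1 of 14, 0.735), with adjusted p again from an estimated correlation. The neutrophil mean was 0.41 in this pool and 0.31 in the highest WT QSC pool. Macrophage (median 0.08) and endothelial markers (0.03) were not called.

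Which genes passed in the Rptor KO QSC pool depended on the WT pools that set the spread. Without WT CSC pool 1, 2 or 3 the 17 genes became 5, 2 and 2, and without WT QSC pool 2 they became 46. Ccna2 and Mki67 passed in each of these fits. Gpnmb then had adjusted p = 0.0643, 0.0751 and 0.106, Mcoln2 0.0584, 0.0751 and 0.0803, Cox8b 0.0643, 0.101 and 0.0861, Bub1 0.0643, 0.0794 and 0.0818 and Fdps 0.0643, 0.0751 and 0.0818 without WT CSC pool 1, 2 and 3. Top2a and Anln each had 0.0519 and 0.0527 without pool 2 and 3, and Idi1 passed without WT QSC pool 3 (0.0266). Camera called 16 lists, 10 without WT QSC pool 3, and fry 0.

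The Rptor KO QSC change correlated weakly and negatively with the WT response to injury, with a sign that turned without WT QSC pool 3. The correlation across genes was -0.105, and 0.0589 and -0.160 without WT QSC pool 3 or WT CSC pool 1. The covariance was -0.0178 (0.0149 in simulated unchanged groups). That of cMet KO QSC, with no gene past the threshold, also lay below its simulated value (-0.00409 against 0.0149). That of TSC1 KO QSC lay above its own (0.0184 against 0.0148). The same sign was seen for 41.8% of the 2510 genes, 30.3% of those that rose in WT CSC and 58.4% of those that fell. Of the 12 genes that fell past the threshold in Rptor KO QSC, 9 had risen in WT CSC, where independent lists would share 1.28.

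Loss of cMet without injury left no gene past the threshold (limma, 0 of 13956, 1 pool against 3). At an unadjusted p under 0.05 there were 185, where 698 are due by chance. So few can mean that the spread taken from the WT pools is too wide for this pool, so that changes could be missed. Asns (1.75 ± 0.28), the glutaredoxin Glrx (1.29 ± 0.23) and the apolipoprotein Apod (0.92 ± 0.18) had the smallest p among higher values, each with adjusted p = 1. Endothelial markers were all 14 positive (median 0.38, 0 adjusted over the list alone), with Fabp4 at 0.68 ± 0.27, and were called higher (adjusted p = 0.750 with an estimated correlation). The ATF4 list was called higher (median 0.16, 1 of 27 adjusted over the list alone, 0.675) and cytosolic ribosomal proteins lower (median -0.16, 0 of 55, 0.675), with Rps21 at -0.64 ± 0.20. Fibro-adipogenic markers were called higher (median 0.15, 0 of 14 adjusted over the list alone, 0.675) and mature fibre markers lower (-0.25, 0 of 14, 0.750). The sex-linked list, in which the Y-linked Eif2s3y, Kdm5d and Uty were tested, was called higher (median 0.44, 0 of 3 adjusted over the list alone, 0.675); its mean was 0.42 in this pool and 0.39 in WT QSC pool 2. Camera called 12 lists and fry 0. The correlation with the WT response was -0.045 across genes (0.0650, 0.160 and -0.0175 without WT QSC pool 2, 3 or 1) and the covariance -0.00409 (0.0149 simulated). The share with the same sign was 48.8% (63.5% without WT QSC pool 3), 56.4% of the genes that rose in WT CSC and 37.9% of those that fell. The count of 0 was 2 with the pool as a random block and 58 with each array counted as a replicate. The cMet mice also differ in strain, being mixed C57BL6 and FVB per the labels.

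Without Rptor, cells opposite an injury differed from Rptor KO QSC in 36 genes, all higher (limma, 1 pool against 1; 706 at an unadjusted p under 0.05). They included cell cycle and macrophage genes: Anln rose by 3.16 ± 0.21, Ccna2 by 3.02 ± 0.23, Mki67 by 2.47 ± 0.23 and Top2a by 2.34 ± 0.22 (adjusted p from 0.00151 to 0.00691), and the complement receptor C3ar1 by 3.29 ± 0.29, the perforin family member Mpeg1 by 2.96 ± 0.30, cathepsin S, Ctss, by 2.95 ± 0.31 and the immune adaptor Tyrobp by 2.43 ± 0.28 (0.00567 to 0.0125). In the cell cycle list 11 of 36 genes rose (27 adjusted over the list alone, median 1.01, adjusted p = 0.0823 with an estimated correlation). Part of this rise comes from the low Rptor KO QSC pool, in which Ccna2, Mki67, Top2a and Anln had fallen against WT QSC. Relative to WT QSC, the mean of this list was -0.58 in Rptor KO QSC, 0.61 in Rptor KO CSC and 1.68 in WT CSC. In the macrophage list 3 of 14 rose (13 adjusted over the list alone, median 1.96; adjusted p = 0.147 with an estimated correlation), and endothelial and neutrophil markers, both called lower, had medians of -0.51 and -0.38 (0 adjusted over the list alone, 0.583 each). Immediate early genes were called lower (median -0.50, 0 of 33 adjusted over the list alone, 0.525), with Junb at -1.04 ± 0.25, the proteasome higher (0.39, 0 of 31, 0.489), and so were the NRF2 list (0.32, 2 of 20, 0.0823), with Pgd at 1.41 ± 0.28, and oxidative phosphorylation (0.19, 0 of 73, 0.559). Among lower values Cebpd was nearest to the threshold (-1.48 ± 0.24, adjusted p = 0.0552, and 0.0466 without WT QSC pool 1). Pgd passed without WT QSC pool 2 (0.0399).

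Without WT CSC pool 1, 2 or 3 these 36 genes became 19, 18 and 15, of which 19, 17 and 15 were among the 36, and without WT QSC pool 2 they became 55. Camera called 17 lists and fry 2, cell cycle and NRF2 (adjusted p = 0.0278 and 0.0474).

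The Rptor KO change resembled that of WT, with a lower slope. This comparison shares no arrays with the WT one. The correlation across genes was 0.617 (0.542 with no filter on dim genes, and -0.001 in simulated unchanged groups), the covariance 0.102 (-5.32e-05 simulated), and 90.4% of the 2510 genes had the same sign. The slope on the WT change was 46.6% over these genes, whose selection alone can lower it. As a check chosen after the data were seen, 1 WT QSC and 1 WT CSC pool were held out in 9 ways and the WT change and its genes taken from the other pools. The held-out WT pools then gave slopes of 69.8% to 104% and the Rptor KO pools 42.6% to 49.7%, lower in all 9, which share pools and are not independent. Macrophage markers had a mean of 2.02 above WT QSC in the Rptor KO CSC pool. Whether carried-over cells lowered the slope was not tested. Of the 36 genes 23 had risen in WT CSC, where independent lists would share 3.83. The difference between the responses itself was past the threshold for no gene (limma, 0 of 13956; 620 at an unadjusted p under 0.05). Its smallest p values were C3ar1 (2.97 ± 0.33), Ctss (3.03 ± 0.36), Mpeg1 (2.85 ± 0.34) and Trem2, a macrophage receptor (1.94 ± 0.24), each with adjusted p = 0.0662, and on the lower side Akr1b8 (-1.74 ± 0.25, 0.0974), Prrg4 (-2.14 ± 0.33) and Eno3 (-2.23 ± 0.34, 0.114 each). The count of 0 was 10 with arrays centred on their medians and 49 with the pool as a random block. Without WT QSC pool 2 it was 19, with Ctss and Mpeg1 (0.00942 each), C3ar1 (0.0290), Trem2 (0.0293) and Eno3 (0.0481) past the threshold.

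**Figure D5:**
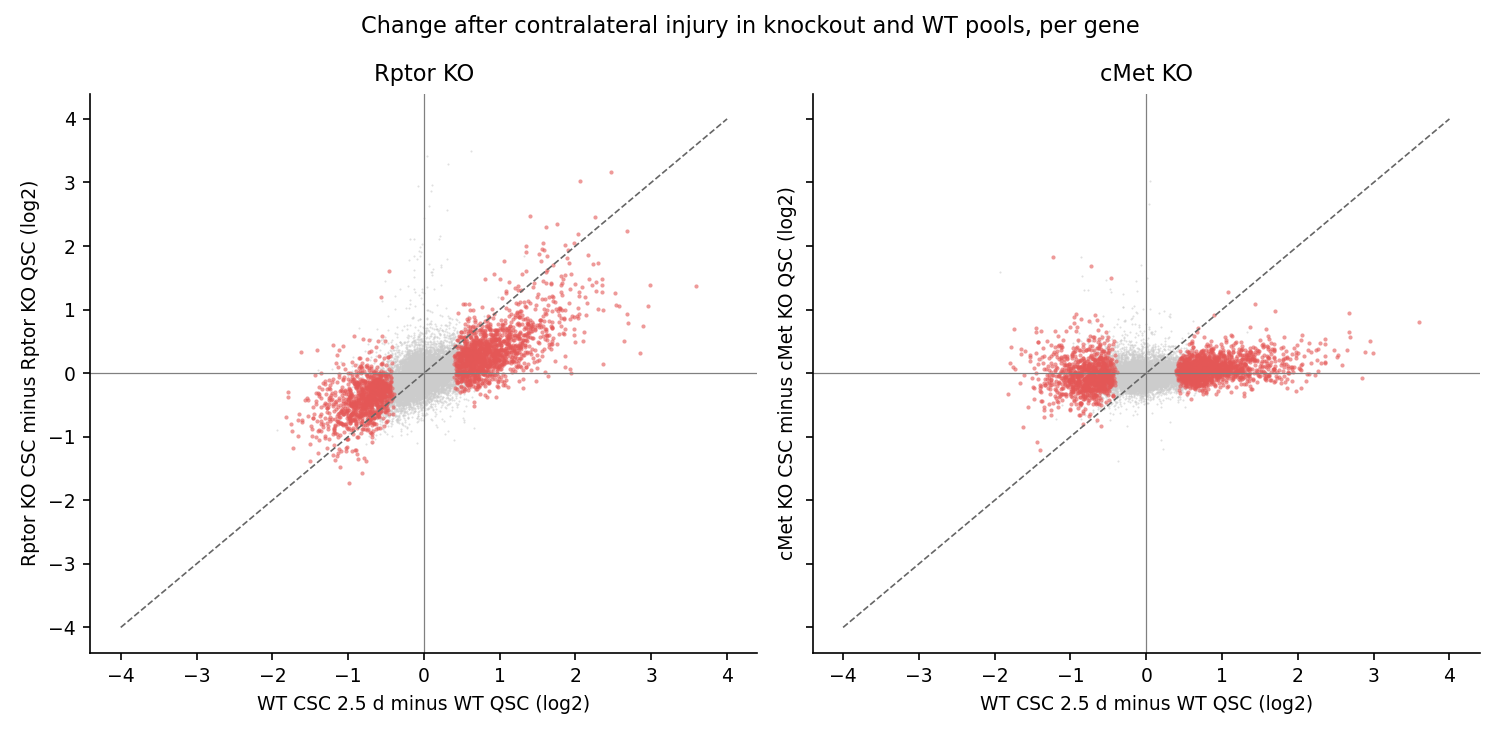
Change after contralateral injury in the Rptor KO pools (left) and the cMet KO pools (right) on the y axis against the WT change at 2.5 days on the x axis, both in log2, with 1 point per gene and the dashed line at equal change. Red points are the 2510 genes past the threshold in WT, of which 90.4% have the same sign in the Rptor KO and 65.1% in the cMet KO.

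By gene group, camera called the Rptor KO response lower than that of WT in the mitochondrial ribosome (median difference -0.48, 0 of 76 adjusted over the list alone), oxidative phosphorylation (-0.43, 0 of 73) and the cell cycle list (-0.71, 10 lower and 2 higher of 36), each with adjusted p = 0.459 with an estimated correlation. It called macrophage markers higher (2.08, 14 of 14 adjusted over the list alone, adjusted p = 0.458 with an estimated correlation). No member of these 4 lists passed over all genes, and of 35 lists fry called 0. Of the other marker lists, mature fibre was also called lower (-0.66, 1 of 14 adjusted over the list alone), and pericyte (0.51), endothelial (0.46), lymphocyte (0.38) and fibro-adipogenic markers (0.31) higher, with 0 adjusted over the list alone in each. With an estimated correlation adjusted p was 0.459 for pericyte markers and 0.540 for the rest of these. Centring arrays moved the median of all genes in this comparison by 0.11, with no change of sign in a called list.

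In the cMet knockout no gene passed between CSC and QSC (limma, 0 of 13956, 1 pool against 1). At an unadjusted p under 0.05 there were 75, where 698 are due by chance. The spread taken from the WT pools may thus be too wide for these pools, so that changes could be missed. The chemokine gene Ccl17 (1.50 ± 0.22) and the leukocyte gene Cd53 (1.49 ± 0.23, adjusted p = 0.816 each) and H2-Aa (1.69 ± 0.30) had the smallest p. Macrophage markers had a median of 0.65, positive in 14 of 14 (adjusted p = 0.512 with an estimated correlation), endothelial markers of 0.32 (0.580) and cell cycle genes of 0.17 (0.556), with 0 adjusted over the list alone in each. Fibro-adipogenic (0.20, 0 of 14 adjusted over the list alone, 0.639), neutrophil (0.14, 0 of 5, 0.639) and lymphocyte markers (0.13, 1 of 4, 0.577) were also called higher. By list mean relative to WT QSC, oxidative phosphorylation went from -0.11 in QSC to 0.03 in CSC, NRF2 from 0.16 to 0.31 and quiescence from -0.09 to -0.26, each in the WT direction. Inflammatory (-0.07 to 0.06), interferon (0.12 to 0.28) and ATF4 genes (0.25 to 0.08) went against it. Camera called 18 lists and fry 0. The correlation with the WT response was 0.186 across genes (-0.001 in simulated unchanged groups), and the covariance 0.0163 (-4.86e-05 simulated). Differences of 2 WT QSC pools reached correlations of 0.0149, 0.168 and 0.191 in size, so that 0.186 does not stand beyond no change. The slope was 7.85% (6.99% to 8.49% with WT pools held out), with the same sign for 65.1% of the 2510 genes. The count of 0 was 2 with the pool as a random block and 30 with each array counted as a replicate.

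The cMet KO response was smaller than that of WT by a direct test, with 22 genes past the threshold, 17 lower and 5 higher (limma; 1328 at an unadjusted p under 0.05). Eno3 differed by -2.79 ± 0.34, Prrg4 by -2.55 ± 0.33, D17H6S56E-5 by -2.25 ± 0.28, the potassium channel Kcnn4 by -2.24 ± 0.32 and Kif20a by -2.24 ± 0.25. H2-Aa (2.42 ± 0.34), Adgrl4 (2.04 ± 0.30), Cd53 (1.96 ± 0.27), Sparcl1 (1.77 ± 0.25) and Spata4 (1.73 ± 0.25) were higher, and adjusted p was 0.0487 for these 10 genes. In the cell cycle list 6 of 36 genes had a lower response (30 adjusted over the list alone, median -1.63, adjusted p = 0.175 with an estimated correlation). The mitochondrial ribosome (median -0.65, 18 of 76 adjusted over the list alone) and oxidative phosphorylation (-0.44, 0 of 73) were called lower, and immediate early (0.82, 0 of 33) and inflammatory genes (0.60, 9 of 27) higher. So were endothelial (1.35, 10 of 14) and macrophage markers (0.59, 2 of 14). With an estimated correlation adjusted p was 0.240 for these lists and 0.379 for the macrophage markers. Fibro-adipogenic (0.61, 4 of 14 adjusted over the list alone, 0.240), pericyte (0.61, 3 of 11, 0.321) and lymphocyte markers (0.45, 1 of 4, 0.379) were called higher too, and mature fibre markers lower (-0.74, 1 of 14, 0.407). Met itself had a lower response (-0.92 ± 0.27) that did not pass (adjusted p = 0.257).

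These 22 calls lie close to the threshold. None was left without WT QSC pool 1 or 3 or WT CSC pool 1, 2 or 3, where the smallest adjusted p of the 10 named genes was 0.0636, 0.0761, 0.109, 0.132 and 0.176, and without WT QSC pool 2 there were 43. With no filter on dim genes, or a stricter filter at the 50th percentile, the count was 0, as it was without 3 second arrays that differed alike from the first, chosen after the data were seen. With arrays quantile normalized again it was 11. Camera called 24 lists and fry 1, the cell cycle list (adjusted p = 0.0183).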

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

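Of the tests given here, 5 were chosen only after the result was seen: the comparison with Rptor KO QSC, the gap between endothelial and macrophage markers, the immediate early genes at 28 days, the swap of the cMet KO pools and the number of cell cycle genes with a lower response.

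The difference between genotypes in the response to contralateral injury was tested directly. Between the Rptor KO and WT responses no gene passed (limma; 620 at an unadjusted p under 0.05, where 698 are due by chance) and fry called 0 lists, while camera with its preset correlation called 23 of 35, and none with an estimated correlation. Between the cMet KO and WT responses camera called 24 lists, again none with an estimated correlation, and 22 genes passed, a count that was 0 without WT QSC pool 1 or 3 or WT CSC pool 1, 2 or 3 and 43 without WT QSC pool 2. It was also 0 without 3 second arrays (a setting chosen after the data were seen), with no filter on dim genes and with a stricter filter. Among the 22, H2-Aa (2.42), Adgrl4 (2.04), Cd53 (1.96), Sparcl1 (1.77) and Spata4 (1.73) had a higher response in the cMet KO, and Eno3 (-2.79), Prrg4 (-2.55), D17H6S56E-5 (-2.25), Kcnn4 (-2.24) and Kif20a (-2.24) a lower one. Camera also called endothelial and macrophage markers higher in the cMet KO response than in that of WT. Each knockout response rests on 1 pool against 1.

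In the Rptor KO CSC pool 12 of the 14 tested macrophage markers were higher than in each of the other 11 pools, abundant ones such as Lyz2 (lysozyme, 12.60 against 8.93 in WT QSC) and Cd68 (10.95 against 9.09) included, and no other list holds any of the 14. The count restates the rise, so that macrophages carried over in the sort for YFP, a gate that would remove cells without the tracer, cannot be told apart from a change in the sorted cells: no macrophages were measured by themselves. The pool's lower array stood at 1.95 above WT QSC, which argues against a fault of 1 array, and Rptor KO QSC stood at 0.052 with the highest WT QSC pool at 0.24, which argues against loss of Rptor without injury. A change in muscle stem cells themselves, with injury and loss of Rptor together, was not tested.

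Of the 14 endothelial markers 12 had all 3 WT CSC pools below all 3 WT QSC pools, abundant ones such as Cdh5 (9.03 against 10.69) included, and no other list holds any of the 14. This count restates the fall in the same way, so that fewer endothelial cells carried through the YFP sort cannot be told apart from lower expression in the sorted cells. Fibro-adipogenic (mean -0.57) and pericyte markers (-0.66) were called lower in the same pools, so that a loss of several cell types together also stays open. An equal fall in the share of all other cell types would lower macrophage markers alike, but the endothelial change lay 1.05 below theirs (-1.05). In this gap the 3 CSC pools stood at -1.28, -0.86 and -0.998 and the QSC pools at -0.17, 0.04 and 0.13. Means of lymphocyte (-0.24), neutrophil (-0.21) and Schwann cell markers (-0.17) were also below WT QSC, and that of mature fibre markers above it (0.75). The gap therefore argues only against an equal fall. Whether lost endothelial RNA could account for the fall of the immediate early genes stays open. At 28 days, with endothelial markers as low, the immediate early genes stood at -0.11 against -0.76 at 2.5 days, but that is a single pool. Neither a fall in the stem cells themselves nor a difference in handling was tested.

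For the weak response of the cMet KO CSC pool, a swap with the cMet KO QSC pool is argued against by the cell cycle mean of the latter, 0.060 above WT QSC where WT CSC stands at 1.68. Too few pools to detect a response of the WT size would leave few differences, but 30 of 36 cell cycle genes had a lower response adjusted over the list alone. These genes can vary together, so that they are not independent differences, and camera with an estimated correlation did not call the list, while fry did. By list mean the cMet KO CSC pool stood at 0.25, the WT CSC pools at 1.64 to 1.76 and the WT QSC pools at -0.15 to 0.09. The lower response of this list thus exceeds the spread of the WT pools, but rests on 1 pool against 1. A CSC pool without a contralateral injury cannot be told apart from a weaker response: the correlation with the WT response was 0.186, and that of a difference of WT QSC pools reached 0.191 in size. Loss of cMet and the mixed strain of these mice, which the design joins, also stay open. Both cMet KO pools, WT QSC pool 2 and the 28-day pool shared small median differences between paired arrays (0.055 to 0.087, elsewhere 0.125 to 0.195). They also shared high values of the Y-linked Eif2s3y (9.94 to 10.37, elsewhere 8.96 to 9.58). Whether these pools were processed together, and whether that mattered, was not tested. Means of macrophage (0.76), endothelial (0.72), neutrophil (0.48) and fibro-adipogenic markers (0.39) lay above WT QSC in this CSC pool, and that of mature fibre markers below it (-0.44). Whether carried-over cells weakened the response was not tested.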

How the results depend on the processing

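Leaving out 3 second arrays was chosen after the data were seen. Single-pool groups were assumed to vary like the WT pools, as was a group left with fewer pools. The arrays give no background signal here, so that the level at which dim genes become unreliable is not known. Of 2581 values of named genes under alternatives, 2284 kept direction and side of the threshold, 138 lost the threshold, 156 gained it and 3 changed direction: Ccnd1 (-0.069) and Myog (-0.13) in WT CSC without WT QSC pool 2, and Rptor (0.090) in Rptor KO QSC without WT QSC pool 1. Over the pools left out these genes ranged from -0.069 to 0.31, -0.13 to 0.86 and -0.24 to 0.090. The cause of the changes below was not tested, unless named. No list that camera called both as reported and after quantile normalization, with no filter, with the mean of all probesets, with the first array alone or without 1 WT pool changed direction. Centring turned the median of no called list, and other settings were not compared list by list.

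With every array counted as a replicate, which takes arrays of a pool for independent, genes past the threshold numbered 5794 (WT CSC), 496 (28 days), 1459 (TSC1 KO), 2306 (Rptor KO QSC), 58 (cMet KO QSC), 762 (Rptor KO CSC against QSC), 30 (cMet KO CSC against QSC), 648 (Rptor KO response minus WT) and 1955 (cMet KO response minus WT). With the pool as a random block (correlation 0.598) they numbered 52 (28 days), 174 (TSC1), 235 (Rptor KO QSC), 2 (cMet KO QSC), 112 and 2 (CSC against QSC, Rptor and cMet) and 49 and 357 (responses minus WT). With the first array alone they were 10 (TSC1), 61 (Rptor KO CSC against QSC) and 11 (Rptor KO response minus WT), and without the 3 second arrays 11 (Rptor KO QSC), 10 and 0 (Rptor and cMet KO response minus WT). Main counts were 2510, 0, 2, 17, 0, 36, 0, 0 and 22.

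Quantile normalization gave 6 (TSC1), 35 (Rptor KO QSC), 4 and 11 (Rptor and cMet KO response minus WT). Centring gave 9, 44, 63 (Rptor KO CSC against QSC), 10 and 62 in that order. The share of higher calls was 43.4% centred against 59.1% in WT CSC, 88.9% centred against 100% for TSC1, and 42.9% quantile normalized against 29.4% for Rptor KO QSC. No filter gave 1 (TSC1) and 0 (cMet KO response minus WT), the filter at the 50th percentile 6, 33 (Rptor KO QSC) and 0, and trend with robust options 10 (TSC1), 12 and 52 (responses minus WT).

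Leaving out 1 WT pool at a time gave 1194 to 2620 genes (WT CSC), 1 to 231 (TSC1), 2 to 46 (Rptor KO QSC), 15 to 55 (Rptor KO CSC against QSC), 0 to 19 and 0 to 43 (responses minus WT), and 10 to 16 lists (Rptor KO QSC). Fewer pools also leave fewer degrees of freedom. Camera with an estimated correlation called 0 lists in each of 9 contrasts. Fry called 0 except 18 in WT CSC, 2 in Rptor KO CSC against QSC and 1 in the cMet KO response minus WT.

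With 1 WT pool left out at a time, each with its own response genes, the share with the WT sign ranged from 60.2% to 69.4% (TSC1, 62.1% with all pools). For cMet KO QSC it was 52.2% to 63.5%, all above the 48.8% with all pools, and 58.0% over the 100 highest and 100 lowest genes. The correlation ranged from -0.160 to 0.0589 (Rptor KO QSC), -0.0501 to 0.160 (cMet KO QSC) and 0.576 to 0.627 (Rptor KO response). The last was 0.542 with no filter and 0.661 at the 50th percentile, and its share of the same sign 97.5% over the 100 highest and 100 lowest genes.

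WT pools share replicate numbers, and deviations of same-numbered pools correlated at 0.319, -0.0331 and -0.0342. Differently numbered pools gave -0.306 to 0.317, so that this check neither shows nor excludes pairing. With the replicate number as a block 2796 genes passed (2370 of the 2510) and camera called 22 lists. The 6 WT pools alone gave 2510.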

Other observations

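The tests of the sterol genes here, and the direct comparison of the TSC1 KO and Rptor KO pools, were chosen only after the result was seen, as were the values of the Dlk1 neighbourhood outside Rptor KO QSC and without single WT pools.

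A group of imprinted genes stood apart in the Rptor KO QSC pool. Of 38 tested genes between Dlk1 and Dio3 in the reference's gene order (32 of them microRNA genes, 103 genes in the table), 97.4% were higher there than in each WT QSC pool, with a median of 1.12. Dlk1 stood at 1.87 and the long noncoding RNA Meg3 at 0.71. The pool's arrays gave 1.11 and 0.90. The same genes had a median of -0.68 in TSC1 KO QSC and -0.70 in WT CSC at 2.5 days, negative for all 38 in both. Of them 22 fell past the threshold in WT CSC (limma, 3 pools against 3) and 0 passed in TSC1 KO QSC. In the other pools they lay nearer to WT QSC, with medians of 0.12 (Rptor KO CSC), -0.15 (WT CSC at 28 days), -0.06 (cMet KO QSC) and -0.20 (cMet KO CSC). The microRNAs Mir485 and Mir134 alone passed in Rptor KO QSC, close to the threshold (adjusted p = 0.0471 each). Mir485 missed it without WT QSC pool 1 (0.0851) or WT CSC pool 1, 2 or 3 (0.0884, 0.147 and 0.158), and Mir134 without WT QSC pool 1 or 3 (0.0859 and 0.0687) or WT CSC pool 1, 2 or 3 (0.0584, 0.147 and 0.143). A shared change of the neighbourhood may lie behind both values, and 1 pool cannot separate it from the genotype.

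Of the 27 sterol and fatty acid genes, 24 lay above the WT QSC mean in TSC1 KO QSC and below it in Rptor KO QSC. This count restates the observation, so that it cannot tell whether opposite mTORC1 activity is behind it. Their mean difference between the pools was 1.32 (adjusted p = 0.474 with an estimated correlation), but mature fibre markers differed by 1.33, with 13 of 14 opposed in the same way, and myogenic genes by 1.14 (0.711 each). Over all genes the changes opposed each other, with a covariance of -0.0298 against 0.0148 in simulated unchanged groups (highest 0.0163) and a correlation of -0.244 against 0.250. The simulation drew each gene by itself, so that its narrow range does not cover genes that vary together between pools. On the second principal component TSC1 KO QSC stood at 35.7 and Rptor KO QSC at -26.4. WT QSC pool 1 (19.8) also parted there from WT QSC pools 2 and 3 (-4.18 and -5.65). In a direct comparison of the pools 216 genes passed (limma), 176 higher and 40 lower in TSC1 KO, with Ccna2 at 2.89 and Mki67 at 2.69. Cox8b was higher in both knockouts than in WT QSC. With 1 pool per genotype, a difference between pools remains possible.

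Splits of the 6 WT pools into 3 and 3 number 10, too few for a share under 0.05: 1 of the 10, the real one, gave 2510 genes, and the highest of the others gave 0.

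Second arrays differed from first arrays alike in WT CSC pool 1, Rptor KO QSC and Rptor KO CSC. The differences correlated across genes at 0.621 to 0.687 among these 3 pools and at -0.358 to 0.258 in the other 33 pairs of pools. In the second arrays 576 genes were lower and 160 higher by more than 0.5.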
